A study of Mus musculus with 32 samples.

How the data were processed

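Prefrontal cortex RNA was measured on 32 one-colour spotted cDNA arrays from 64 mice, and the labels name the sex, line, selection replicate, treatment and pool of every array. Per the labels' protocols, total RNA was extracted with RNA STAT-60 and treated with DNase, 2.5 µg from each of 2 mice was pooled, and cDNA labelled with 33P was hybridised. EtOH mice received an ethanol injection of 1.5 g/kg, or 1.75 g/kg in selection replicate 2 of WSP, before vapour, and all mice received pyrazole at 68.1 mg/kg, per the labels. The imager, the spot-finding software and the array maker are not given in the sources used here.

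Per the file headers, each array's file holds a spot intensity (Signal) and 1 background intensity for the whole array, with no background subtracted by the authors. The authors' series value table holds log2 values as deposited: each column has a rank correlation of 1 with that array's Signal and is blank where Signal is below background. Its column medians ran from 7.39 to 8.58, and 10.9% to 47.3% of values were blank. In the order of arrays 1-1, 1-2, 2-1 and 2-2 the medians were 8.11, 8.25, 8.00 and 8.29 for female WSP air, 8.04, 7.88, 7.95 and 7.89 for female WSP EtOH, 7.86, 7.73, 8.19 and 8.03 for female WSR air, and 7.84, 7.52, 8.58 and 8.03 for female WSR EtOH. They were 7.70, 7.56, 7.72 and 7.55 for male WSP air, 7.59, 8.01, 8.06 and 7.58 for male WSP EtOH, 7.47, 7.49, 7.50 and 7.79 for male WSR air, and 7.69, 7.39, 7.74 and 7.66 for male WSR EtOH. Its log2 scale was found from the scanner values and its direction is that of Signal, while the centring and the scaling that depends on intensity stay unknown. That table was used as an alternative.

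Signals were corrected by normexp with an offset of 50 over all 5355 spots, 4696 clone spots were kept, and these were quantile normalised and put on the log2 scale. The 192 genomic DNA control spots and 467 spots without identity were left out of the tests. Every clone has 1 spot. Of the clones, 1236 were above background on every array and 0 on none. Probe means ran from 5.75 to 11.9 with a median of 5.98, close to the floor of 5.64 that the offset sets, so differences of dim probes are compressed. Median log2 values before scaling ran from 5.80 to 6.23. A probe above background on no array of a group is given as a bound: the brighter group's mean against the dim group's mean of, per array, the higher of its own value and the lowest signal above background, on normalised log2 values. Such a bound describes the measured means, and it takes no account of the spread between arrays.

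Comparisons used limma 3.58.1 in R 4.3.3 (lmFit over 8 group means and all 32 arrays, eBayes with a trend, 24 residual and 5.60 prior degrees of freedom), 2-sided, with Benjamini-Hochberg adjustment over all probes at a threshold of 0.05. Selection replicates were collapsed, as the series' design text states. Gene lists were tested with camera in limma at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over the lists within a comparison: 0 of 273 tests passed under any of the 3. Median, mean and test differed in sign in 69 of 273. Of 34 lists, 21 had at least 5 measured members, and where a gene had several probes the one with the highest mean was used. Gene titles in the files were matched to current symbols by hand for 191 list genes, and ESTs were not named. Array measures were compared by permutation tests with 100000 draws, and similarity between strata by exact permutation. Tables were read with jsonlite 2.0.0 and plots drawn with Python 3.11.15 and matplotlib 3.10.9.

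The comparisons, tests, gene lists, the first group of alternatives given below and the rule for named genes were fixed before the data were examined. By that rule, a comparison names probes with 1 gene title whose mean in the higher group lay above the 25th percentile of probe means (5.87) and whose adjusted p was under 0.05, ranked by size, up to 15 per direction for the average effect, 10 for line, sex and interactions and 5 for each stratum. Where fewer than 5 per direction passed, the 5 with the smallest p are given as values. Members of lists with a call, and the measured sex-linked genes, are added. List members named as examples, the values of Thy1 and others in averages over lines or sexes, and genes named under an alternative were chosen after their values were seen. Counts of calls under 4 normalizations had been seen when titles were matched to symbols and the simulation was run, and no gene's own value had been. The local centring window of 3 spots, the height of 0.75 that defined array sets, and the within-line sex values were chosen after seeing the data.

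Air and EtOH arrays with the same selection replicate number within a line come from the same population, per the labels, so the number pairs them. Deviations from group means correlated between same-numbered air and EtOH arrays at -0.08 in female WSP, 0.21 in female WSR, -0.02 in male WSP and -0.003 in male WSR. Per the labels, pool numbers, and equal numbers in WSP and WSR, share only a number. Even so, each set of arrays described in the Results held a single selection replicate number, mostly across lines or sexes.

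The fits were tested on simulated data with independent normal noise, without array sets or unevenness, and 200 of 4696 probes changed. The sizes were added to the normalised log2 values, on which differences of dim probes are compressed. For the 84.6% of probes with a mean within 1 log2 unit of the floor, a true change shows as a smaller one. Recovery of true changes of these sizes would therefore be lower for them. For sizes of 0.25, 0.5 and 1 log2 units, the percentages recovered were 16.4, 59.7 and 92.4 in female WSP, 26.9, 59.7 and 95.5 in female WSR, 23.9, 74.6 and 93.9 in male WSP, and 25.4, 73.1 and 97.0 in male WSR. They were 70.1, 97.0 and 100 for the average effect, 49.3, 88.1 and 98.5 in females, 46.3, 86.6 and 100 in males, 31.3, 86.6 and 97.0 in WSP, and 38.8, 80.6 and 100 in WSR. They were 16.4, 73.1 and 97.0 by sex, 13.4, 62.7 and 95.5 by line, 46.3, 89.6 and 100 between lines, and 44.8, 86.6 and 100 between sexes.

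Alternatives covered background correction, scaling, the authors' values, dim probes, blocks, array weights, the variance trend, the arrays in the fit, single selection replicates and each array left out in turn. Those added after seeing the data were the random block of array sets, local centring, their combinations with other scalings, and leaving out the 2 arrays of lowest correlation. These 2 arrays were Female WSP Air 2-1 and Male WSP EtOH 1-2. Some members of the fixed lists and 1 gene that the naming rule takes are not reported here.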

Results

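Gene expression was measured in the prefrontal cortex of mice of 2 lines bred selectively for severe or mild withdrawal from ethanol, the Withdrawal Seizure-Prone line (WSP) and its counterpart, the Withdrawal Seizure-Resistant line (WSR). Each line exists as 2 independently derived populations, called selection replicates 1 and 2. Female and male mice breathed ethanol vapour (EtOH) or air for 72 h, and tissue was taken 8 h after the vapour ended, the time the study gives as peak withdrawal. Both treatments included pyrazole, an inhibitor of alcohol dehydrogenase, so the air controls also carried that drug. Every array was hybridised with radiolabelled cDNA from a pool of 2 mice. The 32 arrays, made from 64 mice, formed 8 groups of sex, line and treatment with 4 arrays each, 2 from each selection replicate. Arrays are named by group, selection replicate and pool, as in Female WSP Air 1-2.

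Each array carried 4696 cDNA clone spots, of which 1112 are titled with a named gene and 3584 as expressed sequence tags (ESTs), DNA segments or otherwise unnamed. Signal was low: 84.6% of probes had a mean within 1 log2 unit of the floor that the background correction sets, so log2 differences of dim probes are understated. The share of clone spots above their array's background ranged from 51.1% to 88.7%, with a median of 63.8% over the 32 arrays. Female arrays had a lower background than male arrays, at 16.4 ± 5.94 against 26.5 ± 8.53 intensity units (SD, n = 16 each, 2-sided permutation test p = 3e-04, adjusted over 9 tests 0.00135). The percentage of clone spots above background was 60.9 ± 6.45 on female and 70.5 ± 9.15 on male arrays (p = 0.00156, adjusted 0.00468, same permutation test). Background was 22.1 ± 10.2 on EtOH and 20.9 ± 7.62 on air arrays, a difference that did not pass (permutation p = 0.708, adjusted 0.910). It was 6.97 units higher on WSP than on WSR arrays (SD 10.7 and 4.61, n = 16 each, permutation p = 0.0236), which did not pass after adjustment (0.0532). The number of arrays, 4 in each group, limits the precision of every comparison.

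**Figure D1:**
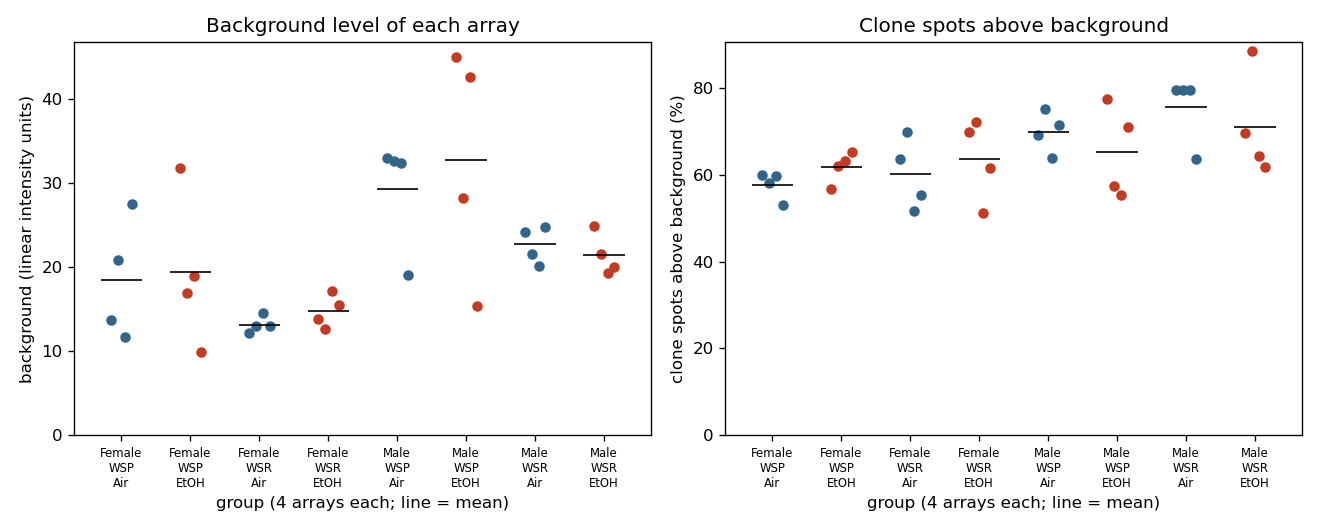
Background level in linear intensity units (left) and percentage of clone spots above background (right) for each of the 32 arrays, as points by group, with the group mean as a line (blue air, red EtOH). Backgrounds reached 45.0 on a male WSP EtOH array and fell no lower than 9.83, on a female WSP EtOH array.

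Arrays from different groups also varied together. Over the 192 genomic DNA control spots, 24 of the 32 arrays fell into 9 sets of more than 1 array, with a mean Spearman correlation of 0.43 within sets and -0.02 between sets. The clone spots, which did not define the sets, followed them: deviations from group means correlated at 0.32 within sets and at -0.01 between sets, over pairs of arrays in different groups. Of the female WSP arrays, 2 of 8 belonged to such a set, against 7 of 8 female WSR, 7 of 8 male WSP and 8 of 8 male WSR arrays. Every such set held arrays of a single selection replicate number, and most sets crossed lines or sexes.

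**Figure D2:**
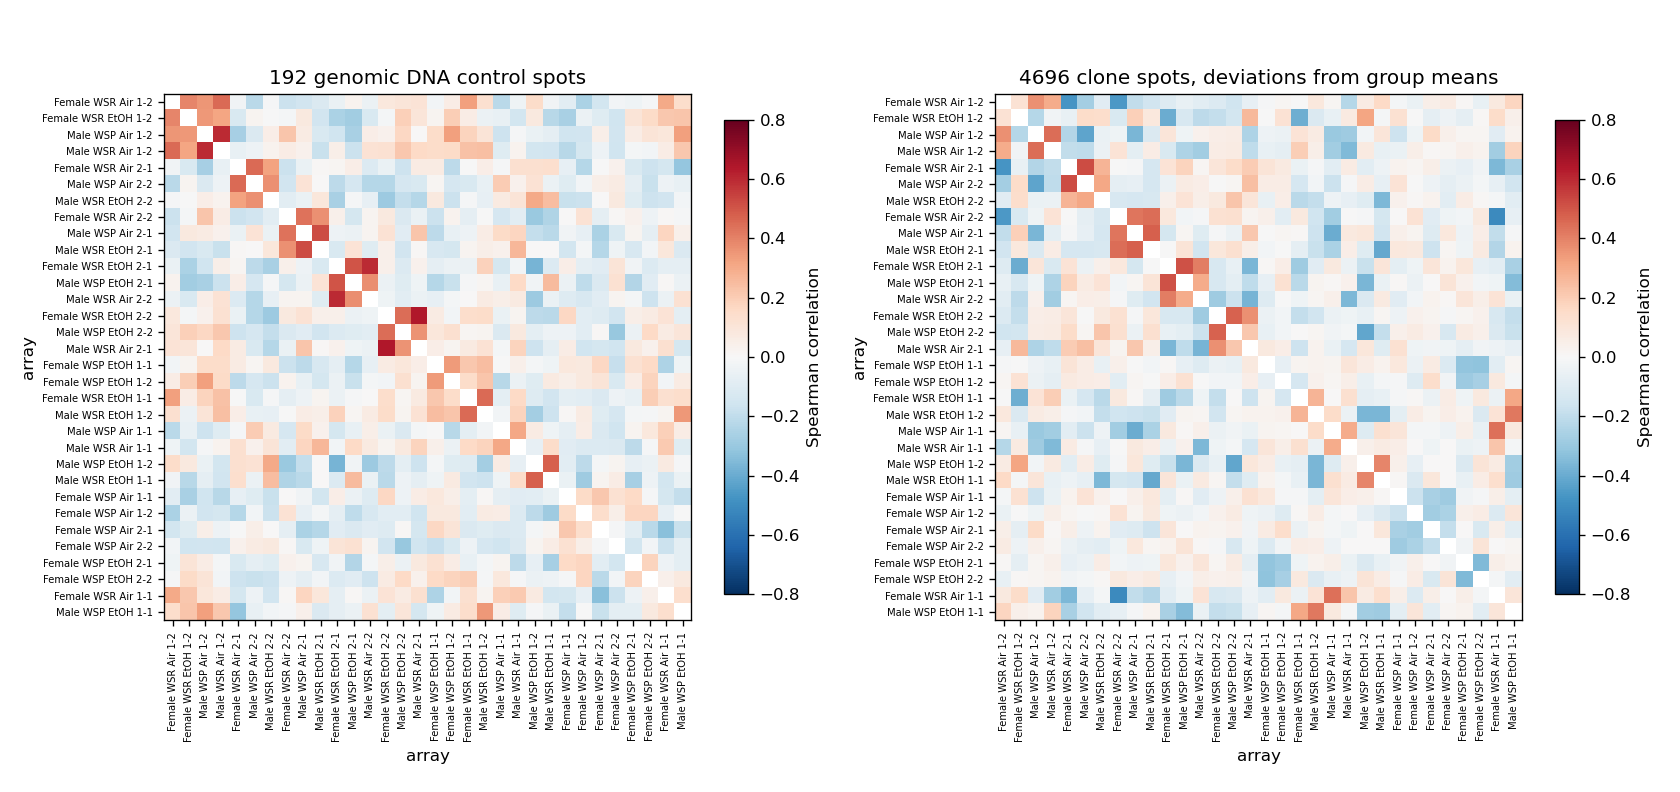
Spearman correlation between all pairs of the 32 arrays over 192 genomic DNA control spots (left) and over the deviations of 4696 clone spots from their group means (right), with arrays ordered by set; colour gives the correlation. The blocks along the diagonal of the control-spot map, which defined the sets, recur in the clone map, with mean correlations of 0.43 and 0.32 within sets.

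The average EtOH effect asks which transcripts differed between 16 EtOH and 16 air arrays over both sexes and lines. Among named genes, the smallest p values belonged to small differences. CDC like kinase 4, a kinase of splicing factors, was 0.18 log2 units higher in EtOH (SE 0.05, n = 16 each), and transforming growth factor, beta induced, 68 kDa, an extracellular matrix protein, was 0.23 higher (SE 0.07). The connexin gap junction membrane channel protein beta 5 was 0.17 higher (SE 0.05), neurofibromatosis 2 interacting protein 0.19 higher (SE 0.05) and transcription factor-like 1 0.14 higher (SE 0.04). On the lower side, the small GTPase Harvey rat sarcoma oncogene, subgroup R differed by -0.12 (SE 0.03), the fibronectin receptor subunit integrin beta 1 by -0.27 (SE 0.09) and the zinc finger factor TGFB inducible early growth response by -0.27 (SE 0.10). MYB binding protein (P160) 1a, a nucleolar protein, differed by -0.13 (SE 0.04) and pleckstrin homology, Sec7 and coiled/coil domains 2, an exchange factor for ARF GTPases, by -0.22 (SE 0.08). Each difference held on 13 to 15 of the 16 EtOH arrays against the air mean. None of the 4696 probes passed the test (limma, smallest adjusted p = 0.656), although 353 had an unadjusted p under 0.05 where 234.8 are expected by chance. Transcription factor-like 1 turned to -0.01 under local centring with median scaling.

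No gene list fixed beforehand passed the camera test for the average effect, which covered 21 lists (smallest adjusted p = 0.405, or 0.407 with an estimated correlation). Of 9 immediate early genes, the transcripts that neurons induce on activation, 3 had higher and 6 lower means in EtOH, with Nr4a2 at -0.11 (SE 0.08), Fosl2 at -0.08 (SE 0.04) and Egr1 at 0.02 (SE 0.07). Among 8 heat shock and chaperone genes, 5 means were higher, led by the chaperonin subunits Cct6a at 0.23 (SE 0.13) and Tcp1 at 0.17 (SE 0.09). Histone and chromatin genes had 9 of 13 means higher, among them the histone gene H3f3b at 0.23 (SE 0.08) and the remodelling subunit Smarcb1 at 0.12 (SE 0.04). Synaptic vesicle genes had 4 of 6 means higher, with Snap23 at 0.15 (SE 0.10) and Vamp2 at -0.11 (SE 0.08), and neuron markers had 4 of 5 higher, with the surface glycoprotein Thy1 at 0.11 (SE 0.05). Cytokine, NF-kB and TNF signalling genes had 8 of 10 means lower (adjusted p = 0.645), and cell cycle genes 8 of 13 lower (adjusted p = 0.432).

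Cell type and stress lists were as uneven. Astrocyte markers had 4 of 6 means higher, with Fgfr3 at 0.24 (SE 0.11), adjusted p = 0.645. Means were higher for 3 of 6 blood and choroid plexus markers (0.914), 4 of 6 mitochondrial respiratory chain genes (0.623), 4 of 8 ribosomal protein genes (0.975), 7 of 12 proteasome and ubiquitin genes (0.914) and 6 of 11 protein kinase and cAMP signalling genes (0.668), with the adjusted camera p in brackets. They were higher for 5 of 7 growth factor genes (0.842), 7 of 15 cytoskeleton and axon growth genes (0.914), 3 of 6 oxidative stress genes (0.936), 3 of 6 endoplasmic reticulum stress genes (0.914) and 2 of 6 pro-apoptotic genes (0.668). They were also higher for 4 of 6 glutamate receptor and transporter genes (0.914), 2 of 5 ion channel genes (0.936) and 2 of 5 neuropeptide genes (0.905). In 4 of these 21 lists the median, the mean and the test differed in sign.

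The remaining 13 lists had fewer than 5 measured members and were described gene by gene. For the average effect, Cyp2e1, an ethanol-oxidising enzyme, stood at -0.04 (SE 0.09, adjusted p = 0.931) and Timeless, listed with the circadian clock, at 0.10 (SE 0.04, adjusted p = 0.656). Among GABA system genes, the vesicular transporter Slc32a1 stood at -0.06 (SE 0.07) and the receptor Gabbr1 at -0.06 (SE 0.09). Glucocorticoid-responsive genes read -0.06 for Bcl6, -0.10 for Tsc22d3 and -0.16 for Cdkn1a (SE 0.04, 0.05 and 0.15). In the steroid hormone receptor and neurosteroid list, Esr1 and Nr1h2 both read -0.15 (SE 0.08 each), with Hsd17b1 at 0.06 and Sts at -0.06. Microglia and macrophage markers read -0.01 for Mpeg1, -0.14 for Fcer1g and -0.02 for Cd14. Vascular markers read -0.06 for Col4a1, 0.12 for Eng and 0.19 for Kcnj8, and myelin list members 0.03 for Nkx6-2 and -0.07 for Enpp2. In the cholesterol and lipid synthesis list, Abca1 read -0.10 and Abcg1 -0.07. Anti-apoptotic genes read -0.11 for Dad1, -0.06 for Mcl1 and 0.04 for Api5, while Ddc read 0.03 and the striatal marker Dlx5 0.04. None of these passed the limma test.

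In female WSP mice, EtOH against air compared 4 arrays with 4. Transforming growth factor, beta induced, 68 kDa was 7.88 ± 0.25 in EtOH and 7.30 ± 0.15 in air (log2 intensity, SD, n = 4 each), a difference of 0.58 (SE 0.13, adjusted p = 0.0753). SPO11 homolog, a meiotic recombination protein, was 0.67 higher (SE 0.16, adjusted p = 0.0816). Gap junction membrane channel protein beta 5 was not above background on any air array and was above it on 3 of 4 EtOH arrays, at least 1.25-fold higher (adjusted p = 0.0753). By the same rule Timeless was at least 1.11-fold and the translation repressor eukaryotic translation initiation factor 4E binding protein 2 at least 1.16-fold higher (adjusted p = 0.188 each). Lower in EtOH were neuropathy target esterase, a neuronal phospholipase, at -0.63 (SE 0.14), and SA rat hypertension-associated homolog at -0.59 (SE 0.13), both with adjusted p = 0.0753. The interferon-induced GTPase guanylate nucleotide binding protein 2 stood at -0.64 (SE 0.19), Mouse 19.5 at -0.51 (SE 0.13) and the replication helicase subunit Mcm4 at -0.37 (SE 0.10), with adjusted p from 0.137 to 0.188. All 4 EtOH arrays lay on the stated side of the air mean for each gene. Guanylate nucleotide binding protein 2 turned to 0.01 within selection replicate 2.

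No probe passed the limma test in female WSP (smallest adjusted p = 0.0523), while 543 had an unadjusted p under 0.05, 267 higher and 276 lower. Neuron markers had 4 of 5 means higher, with Thy1 at 0.29 (SE 0.11), and all 6 mitochondrial respiratory chain genes had higher means, both with adjusted p = 0.680. When adjusted over the list alone, 3 members passed, and 0 over all probes: the immediate early gene Nr4a2 at -0.53 (SE 0.17, limma adjusted p = 0.0323), the potassium channel Kcnk1 at -0.39 (SE 0.13, 0.0261) and Mcm4 (0.0104). Over all comparisons, 273 list tests gave 17 such passes, some of them the same gene in several lists. With no difference at all, a share of about 0.05 of these tests would hold a pass by chance. Such passes, here and below, are therefore not findings about single genes. The count moved with the processing: median scaling called 17 probes (2 higher, 15 lower), cyclic loess 31 (3 and 28) and the authors' values 22 of 2170 (1 and 21). The authors' values differ in more than scaling, as they are blank below background and cover fewer probes. Neuropathy target esterase was called under all 3, at -0.84, -0.84 and -1.59. It was above background on 4 air and 2 EtOH arrays of female WSP, so the last value rests on 2 EtOH arrays. All 3 settings used the same hybridisations and are not independent checks. Leaving out Female WSP Air 1-1 gave 18 calls, Air 2-1 6, EtOH 2-1 4, and Air 1-2 and Air 2-2 2 each.

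In female WSR mice, histone deacetylase 1 (Hdac1), which removes acetyl groups from histones, was not above background on any air array and was above it on 4 of 4 EtOH arrays, at least 1.26-fold higher. Regulator of G-protein signaling 2, a GTPase activator for G alpha subunits, was 0.41 higher (SE 0.13, n = 4 each), ribosomal protein L36 (Rpl36) 0.30 higher (SE 0.12) and gene trap locus 3 0.20 higher (SE 0.08). RIE2 protein was above background on 3 of 4 EtOH arrays and no air array, with no bound above 1. Lower means belonged to Ia-associated invariant chain, a chaperone of class II histocompatibility molecules, at -0.38 (SE 0.14), aquaporin 7, a water and glycerol channel, at -0.56 (SE 0.24), and Blu at -0.48 (SE 0.22). Activator of basal transcription stood at -0.32 (SE 0.14) and hematopoietic zinc finger at -0.13 (SE 0.05). Of 8 heat shock and chaperone genes 4 had higher means, with Cct6a at 0.31 (SE 0.26) and the heat shock protein 40 gene Dnajb1 at 0.28 (SE 0.13), and 10 of 13 histone and chromatin genes did (adjusted p = 0.526 for both lists). Hdac1 passed when adjusted over the list alone (limma adjusted p = 0.0491) and not over all probes. No probe passed (limma, smallest adjusted p = 1.00), and 141 had an unadjusted p under 0.05, fewer than the 234.8 expected by chance. The sign of gene trap locus 3 turned to -0.06 when each array was centred locally.

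In male WSP mice, plakophilin-3, a desmosome protein, was 0.88 higher in EtOH (SE 0.33), on 3 of 4 arrays. The tRNA-modifying enzyme tRNA-guanine transglycosylase was 0.57 higher (SE 0.21), the orphan receptor G-protein coupled receptor 26 0.40 (SE 0.14), the transcription factor musculin 0.39 (SE 0.13) and cyclin G2 0.38 (SE 0.14). The small GTPase ARL6 stood at -0.64 (SE 0.21), the spindle checkpoint kinase Bub1b at -0.48 (SE 0.18) and the protease cathepsin W at -0.42 (SE 0.15). Harvey rat sarcoma oncogene, subgroup R and the protein kinase A anchoring protein D-AKAP2 were not above background on any EtOH array and were at least 1.06-fold and at least 1.03-fold lower there. Cell cycle genes had 10 of 13 means lower, with Wee1 at -0.37 (SE 0.20) and Ccnd1 at -0.17 (SE 0.08), and cytokine and NF-kB genes had 8 of 10 lower, with the chemokine Cx3cl1 at -0.30 (SE 0.18), both with adjusted p = 0.636. No probe passed (limma, smallest adjusted p = 0.751), and 289 had an unadjusted p under 0.05, 109 higher and 180 lower. Plakophilin-3 turned to -0.23 within selection replicate 2.

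In male WSR mice, glutamine synthetase (Glul), the astrocyte enzyme that converts glutamate to glutamine, was 8.60 ± 0.41 in EtOH and 9.12 ± 0.10 in air, a difference of -0.52 (SE 0.16, n = 4 each). The postsynaptic scaffold Homer1 stood at -0.33 (SE 0.09), the calcium channel inositol 1,4,5-triphosphate receptor 1 (Itpr1) at -0.32 (SE 0.10) and beta tubulin 5 (Tubb5) at -0.20 (SE 0.06). MAD homolog 3, which carries TGF-beta signals, was 0.46 higher (SE 0.19), the calcium-binding protein tescalcin 0.42 (SE 0.16) and glycine transporter 1 0.30 (SE 0.12). The potassium channel, subfamily K, member 8 was 0.27 higher (SE 0.11) and the mitochondrial import protein metaxin 0.23 (SE 0.09). When adjusted over the list alone, Homer1 and Glul passed among glutamate receptor and transporter genes (limma adjusted p = 0.00630 and 0.00737), Homer1 among immediate early genes (0.00946), Glul among astrocyte markers (0.0147), Itpr1 among ion channels (0.0159) and Tubb5 among cytoskeleton genes (0.0221), and 0 over all probes. Homer1 and Glul are thus counted repeatedly, and the limit given for female WSP applies. Ribosomal protein genes had 7 of 8 means lower, with Rpl12 at -0.25 (SE 0.24), and endoplasmic reticulum stress genes 5 of 6 lower, with Ppp1r15a at -0.33 (SE 0.17). Blood and choroid plexus markers, a sign of other tissue, had 5 of 6 means higher, with a median of 0.08. All 3 lists had an adjusted p = 0.335 (0.618 with an estimated correlation). No probe passed (limma, smallest adjusted p = 1.00), and 159 had an unadjusted p under 0.05.

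Averages over lines or sexes compared 8 EtOH arrays with 8 air arrays. In females, all 5 neuron markers had higher means in EtOH, with Thy1 at 0.19 (SE 0.08) and Ina at 0.11 (SE 0.09), and all 6 mitochondrial respiratory chain genes did, with Ndufa2 at 0.20 (SE 0.12), both with adjusted p = 0.292. In WSP mice of both sexes, 8 of 9 immediate early genes had lower means, among them Nr4a2 at -0.25 (SE 0.12) and Ier2 at -0.15 (SE 0.12), and 9 of 13 cell cycle genes did, among them Pcna at -0.23 (SE 0.13), both with adjusted p = 0.351. In WSR mice, 7 of 8 heat shock and chaperone genes had higher means, with a median of 0.13, including Cct2 at 0.14 (SE 0.08) and Tcp1 at 0.14 (SE 0.13). That list had the smallest adjusted p of all 273 list tests, 0.163, or 0.232 with an estimated correlation. Its adjusted p ended below the threshold under median scaling and without Male WSR EtOH 2-2, where 1 list was called in each case. In males, Homer1 stood at -0.18 (SE 0.06) and passed when adjusted over the glutamate receptor and transporter list alone (limma adjusted p = 0.0426). No probe passed by limma in any of these averages, and 373 in females, 296 in males, 360 in WSP and 81 in WSR had an unadjusted p under 0.05. Without Female WSP Air 1-2, 2 probes were called in females and 1 in WSP, and without Female WSP EtOH 2-1, 1 in WSP.

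Whether the response to EtOH differed by sex was tested as the female effect minus the male effect. RIE2 protein had the smallest p among named genes (limma adjusted p = 0.259), but it was above background on 11 of 32 arrays and on no array in 2 of the 8 groups, so no size is given. Cyclin-dependent kinase 2 (Cdk2), which drives entry into DNA synthesis, differed by 0.31 (SE 0.11) on its brighter probe and by -0.06 (SE 0.05) on a dimmer one, histidyl tRNA synthetase by 0.38 (SE 0.14), cathepsin J by 0.35 (SE 0.12) and Sh3 domain YSC-like 1 by 0.39 (SE 0.14). Neuropathy target esterase differed by -0.45 (SE 0.14), from -0.39 in females and 0.05 in males, and eukaryotic elongation factor-2 kinase, a brake on translation, by -0.44 (SE 0.18). IL2-inducible T-cell kinase differed by -0.29 (SE 0.12). No size is given for SA rat hypertension-associated homolog and zinc finger protein 46, which were above background on no array in 1 and 2 of the 8 groups. Mitochondrial respiratory chain genes had 5 of 6 differences above 0, with Cox6a1 at 0.37 (SE 0.21), adjusted p = 0.565. No probe passed (limma), and 288 had an unadjusted p under 0.05, 204 higher and 84 lower.

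The corresponding test by line took the effect in WSP minus that in WSR, the contrast of the trait under selection. Glutamine synthetase (Glul) differed by 0.36 (SE 0.16), from 0.20 in WSP and -0.16 in WSR, and Sh3 domain YSC-like 1 by 0.36 (SE 0.14). The adhesion molecule nectin-3 alpha differed by -0.51 (SE 0.22) and Mcm4 by -0.22 (SE 0.10). Myocyte-enriched calcineurin interacting protein 1, an inhibitor of the phosphatase calcineurin, differed by -0.24 (SE 0.10). No size is given for the TPA regulated locus, hematopoietic zinc finger, gap junction membrane channel protein beta 5, prostaglandin E receptor EP4 subtype and metaxin, which were above background on no array in 5, 4, 2, 2 and 1 of the 8 groups. Cell cycle genes had 9 of 13 differences below 0, with Mki67, a proliferation marker, at -0.40 (SE 0.24), adjusted p = 0.766. No probe passed (limma, smallest adjusted p = 0.999), and 98 had an unadjusted p under 0.05.

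The profiles of EtOH effects were compared between strata over all 4696 probes, which are not independent replicates. The Pearson correlation was 0.13 between female WSP and female WSR (exact p = 0.0922, adjusted over 6 pairs 0.372) and 0.33 between female WSR and male WSP (exact p = 0.124, adjusted 0.372). It was -0.06 for female and male WSP (exact p = 0.369, adjusted 0.719) and -0.17 for female and male WSR (0.479, adjusted 0.719). It was 0.07 for male WSP and male WSR (0.838, adjusted 0.896) and 0.01 for female WSP and male WSR (0.896, adjusted 0.896). These 2-sided tests enumerated all 4900 relabellings of treatment within the strata of a pair, and none passed. Array sets join arrays of different strata, so these correlations can carry shared array variation as well as EtOH effects. Female WSR and male WSP arrays of the same set mostly had the same treatment, and female and male WSR arrays of the same set mostly opposite treatments. The part of the sets in these correlations was not tested. Single arrays turned the sign of 3 correlations. That of female WSP and male WSR was -0.0225 without Female WSP EtOH 1-1, -0.0259 without Female WSP Air 2-1, -0.00132 without Female WSP Air 2-2, -0.00826 without Female WSP EtOH 2-2, -0.0254 without Male WSR EtOH 1-2, -0.0410 without Male WSR Air 2-2 and -0.00878 without Male WSR EtOH 2-2. That of male WSP and male WSR was -0.00767 without Male WSP Air 1-1, -0.0330 without Male WSP Air 1-2, -0.141 without Male WSP EtOH 1-2, -0.0634 without Male WSR Air 1-2 and -0.147 without Male WSR EtOH 1-1, and that of female and male WSR was 0.0110 without Female WSR Air 2-2.

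**Figure D3:**
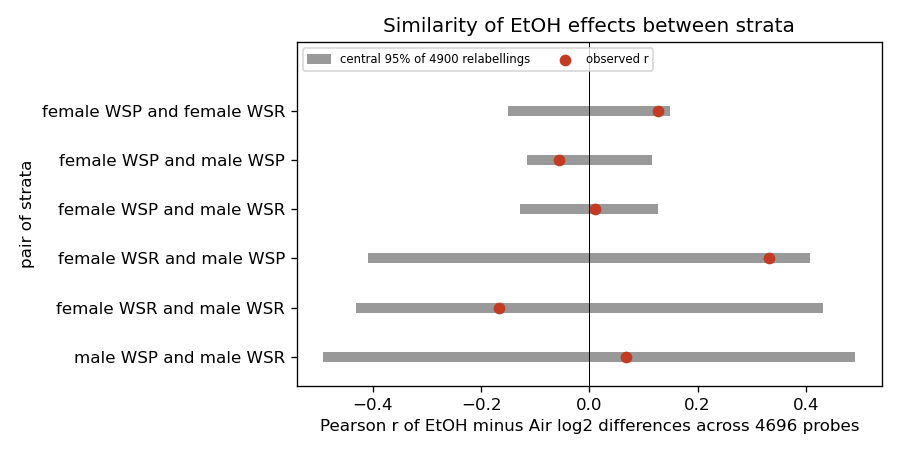
Pearson correlation of EtOH minus air log2 differences across 4696 probes for the 6 pairs of strata (red points), with the central 95% of 4900 relabellings of treatment as grey bars. Every observed correlation, from -0.17 to 0.33, lies inside its bar.

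The lines were compared in air controls, WSP against WSR with 8 arrays each. The small GTPase ARL6, a component of ciliary trafficking, was 7.32 ± 0.36 in WSP and 6.77 ± 0.41 in WSR, a difference of 0.55 (SE 0.15, adjusted p = 0.314), with 8 of 8 WSP arrays above the WSR mean. Myocyte-enriched calcineurin interacting protein 1 was 0.24 higher (SE 0.07), sex comb on midleg-like 1 0.35 (SE 0.11), SA rat hypertension-associated homolog 0.32 (SE 0.09) and suppressor of initiator codon mutations, related sequence 1 0.29 (SE 0.10). Type II iodothyronine deiodinase, which makes active thyroid hormone in brain, was 7.64 ± 0.42 in WSP and 8.08 ± 0.15 in WSR, a difference of -0.44 (SE 0.11, adjusted p = 0.290), with 7 of 8 WSP arrays below the WSR mean. Endonuclease G (Endog), a mitochondrial nuclease, stood at -0.52 (SE 0.15), enhancer of polycomb homolog 1 at -0.38 (SE 0.10), cytokine receptor related protein 4 at -0.39 (SE 0.11) and the DNA damage checkpoint kinase ATR at -0.35 (SE 0.10). Endog passed when adjusted over the pro-apoptotic list alone (limma adjusted p = 0.00724), and 0 members over all probes. Ribosomal protein genes had 7 of 8 means lower in WSP, with Rpl19 at -0.17 (SE 0.14), adjusted p = 0.869. No probe passed (limma, smallest adjusted p = 0.150), and 252 had an unadjusted p under 0.05. Cyclic loess called 3 probes, including ARL6 at 0.65 (SE 0.12), the authors' values 11 of 2170, including type II deiodinase at -0.86 (SE 0.18), and the data without Female WSP Air 1-2 2. A random block of array sets, which are described above with the control spots, called 4, and the fit without a variance trend 2.

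The sexes were compared in air controls, female against male with 8 arrays each, and 15 probes differed (limma, adjusted p under 0.05), 1 higher and 14 lower in females. Transforming growth factor, beta induced, 68 kDa was lower in females, at 7.46 ± 0.21 against 7.90 ± 0.18, a difference of -0.44 (SE 0.09, adjusted p = 0.0355), with 8 of 8 female arrays below the male mean. Golgi SNARE GS15, a vesicle fusion protein of the Golgi, was lower at 7.54 ± 0.38 against 8.06 ± 0.19, a difference of -0.51 (SE 0.11, adjusted p = 0.0355), on 7 of 8 female arrays. The other 13 called probes are ESTs or unnamed, from an EST at -1.37 (SE 0.29, adjusted p = 0.0355) to the single higher one, an EST similar to the CD34 precursor, at 0.40 (SE 0.09, adjusted p = 0.0363). Below the threshold, the sodium pump subunit ATPase, Na+/K+ beta 3 polypeptide stood at -0.32 (SE 0.08, adjusted p = 0.0582), cytokine receptor related protein 4 at -0.38 (SE 0.11) and Dnajb1 at -0.32 (SE 0.09). SA rat hypertension-associated homolog stood at 0.34 (SE 0.09), neuropathy target esterase at 0.36 (SE 0.10) and tumor necrosis factor receptor superfamily, member 7 at 0.25 (SE 0.09). The stress-induced transcription factor Ddit3 stood at 0.24 (SE 0.07) and the DNA exonuclease Trex1 at 0.23 (SE 0.08).

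**Figure D4:**
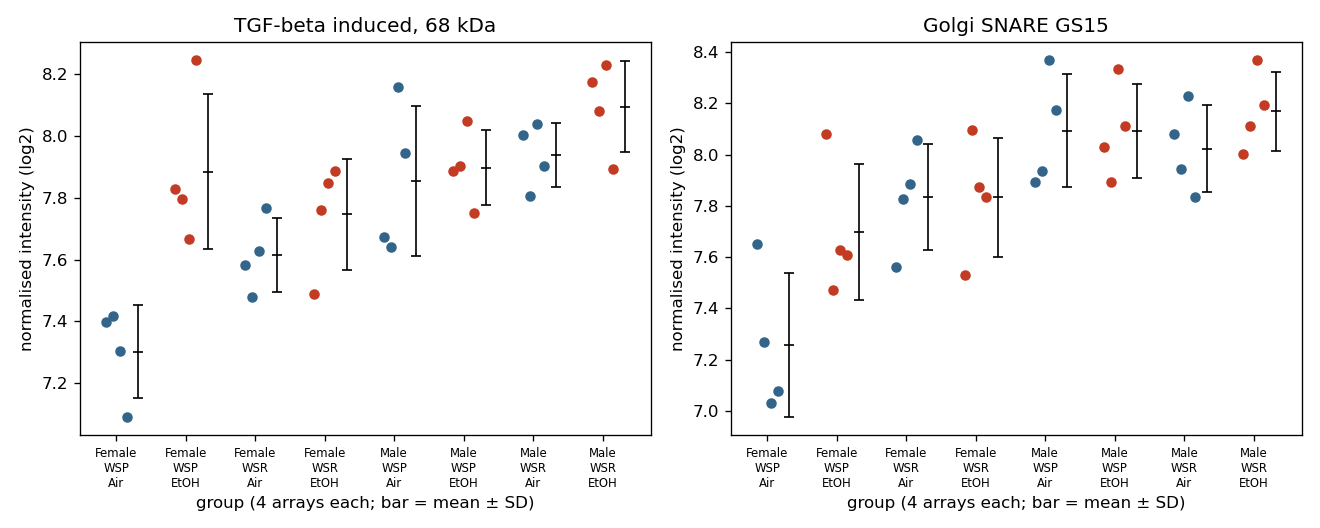
Normalised log2 intensity of transforming growth factor, beta induced, 68 kDa (left) and Golgi SNARE GS15 (right) on each array by group, as points (blue air, red EtOH) with the group mean ± SD of 4 arrays; the vertical axes do not start at 0. Air-exposed females average 7.46 and 7.54 and air-exposed males 7.90 and 8.06 for these genes, and female WSP air arrays are the lowest group in both.

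The sex-linked genes on the array gave a weak check of the labels. The Y-linked translation factor Eif2s3y was 6.21 ± 0.18 in females and 6.42 ± 0.11 in males, a difference of -0.21 (SE 0.10, limma unadjusted p = 0.0456, adjusted p = 0.498). All 8 female arrays lay below the male mean, the direction the labels give, and the spot was above background on 7 of 8 female arrays. Kdm6a, an X-linked histone demethylase, differed by 0.04 (SE 0.04, adjusted p = 0.843). Blood and choroid plexus markers had 6 of 6 means higher in females, with Enpp2 at 0.22 (SE 0.09) and Igf2 at 0.08 (SE 0.03), adjusted p = 0.377 (0.695 with an estimated correlation). When adjusted over the list alone, Ddit3 passed among pro-apoptotic and endoplasmic reticulum stress genes (limma adjusted p = 0.0171 in both), Dnajb1 among chaperones (0.0131), and Homer1, at -0.19 (SE 0.06), among glutamate and immediate early genes (0.0307 and 0.0460), with 0 list members passing over all probes.

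Within lines, all 15 sex calls kept their direction in both WSP and WSR air controls, with a median difference of -0.51 in WSP and -0.33 in WSR. The 15 were chosen on these same arrays, so their direction within lines is not independent evidence. Golgi SNARE GS15 differed by -0.84 (SE 0.16, adjusted p = 0.0127) in WSP and by -0.19 (SE 0.16, adjusted p = 0.999) in WSR, and transforming growth factor, beta induced, 68 kDa by -0.55 (SE 0.13, adjusted p = 0.0677) and -0.32 (SE 0.13, adjusted p = 0.970). The test called 10 probes within WSP, 5 of them among the 15, and 0 within WSR. At an unadjusted p under 0.05 limma gave 496 in WSP and 227 in WSR, where 234.8 are expected by chance. That expectation may be too low for WSP: other splits of the female WSP arrays by treatment gave a median of 398.5. No split by sex within a line was run, so the WSP counts are not shown to exceed chance. Among EtOH arrays all 15 had the same direction and 1 was called, with a median of -0.26 against -0.44 in air. These arrays shared the normalization and the estimate of spread behind the 15 calls, so they are not an independent check either. With only the air arrays in the fit, 6 probes were called, and transforming growth factor, beta induced, 68 kDa and GS15 did not pass (limma adjusted p = 0.0570 and 0.0650). Over the alternatives other than single arrays left out, their limma adjusted p ranged from 0.00395 and 0.00769 to 0.999 each. Among EtOH arrays GS15 differed by -0.37 (SE 0.11, adjusted p = 0.265) and transforming growth factor, beta induced, 68 kDa by -0.18 (SE 0.09, adjusted p = 0.705). The difference between lines or between treatments in these sex effects was not tested for the 15 probes as a set. Sex went together with array background and the percentage of spots above it, and median scaling or cyclic loess called 0 of the 15, which all kept their direction at a median size of 0.35 and 0.33 against 0.44. All 15 were called without background correction and with an offset of 16, at median sizes of 0.66 and 0.61, and 11 after local centring. The authors' values called 138 of 2170 probes, 55 higher and 83 lower. Their columns also differed by sex, with mean column medians of 8.01 on female and 7.66 on male arrays, and 37.6% and 28.5% blank. These calls thus went together with array level as well. Transforming growth factor, beta induced, 68 kDa and GS15 did not pass there (limma adjusted p = 0.135 and 0.0533). The count was 0 without Female WSP Air 2-1, Female WSR Air 1-1, 1-2 or 2-2, Male WSP Air 2-1 or Male WSR Air 1-1, and it was 1 without Female WSP Air 2-2, 2 without Male WSR Air 2-2, 3 without Male WSR Air 2-1, 4 without Male WSP Air 2-2, 6 without Female WSP Air 1-2, 7 without Male WSP Air 1-1 and 8 without Male WSP Air 1-2.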

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

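Chosen only after the results were seen were the tests of array floor and spot position for the sex calls, both tests of the array sets, and the splits by number of called probes; the tests of neighbouring spots and the splits by unadjusted p were set beforehand.

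In 379 tests of array measures and gene values within the 8 groups of 4 arrays, which are not independent of each other, 26 had an array standing apart from the other 3, where chance gives about 1 in 20, or 18.95. Values are the gap to the nearest array as a share of the range. For array measures it was 0.960 for the background of Male WSP Air 2-2 (19.02), 0.846 for the 5th percentile of signal of Female WSR EtOH 2-1 (8.25), 0.993 for the percentage above background of Male WSR Air 2-2 (63.78) and 0.874 for the median correlation of Female WSR EtOH 2-2 (0.979). Hematopoietic zinc finger stood apart on Female WSP EtOH 2-2 (0.983), Male WSP Air 2-2 (0.881), Male WSP EtOH 1-1 (0.882) and Male WSR Air 2-2 (0.839). SA rat hypertension-associated homolog did so on Female WSP Air 1-2 (0.881), Male WSP Air 1-1 (0.879) and Male WSP EtOH 1-2 (0.979), and nectin-3 alpha on Female WSP EtOH 1-1 (0.858), Female WSR Air 2-1 (0.896) and Male WSP EtOH 1-1 (0.893). On Male WSR EtOH 1-1 it was 0.844 for histidyl tRNA synthetase, 0.951 for Sh3 domain YSC-like 1 and 0.844 for calcineurin interacting protein 1. In female WSP air it was 0.900 for zinc finger protein 46 (2-1), 0.945 for suppressor of initiator codon mutations (1-1) and 0.842 for Ddit3 (1-2). In female WSP EtOH it was 0.932 for neurofibromatosis 2 interacting protein (1-1) and 0.949 for guanylate nucleotide binding protein 2 (2-2). It was 0.832 for RIE2 protein (Male WSP Air 2-1), 0.8293 for Mcm4 (Male WSR Air 2-1), 0.897 for ATR (Female WSR Air 2-1) and 0.863 for ATPase, Na+/K+ beta 3 (Male WSR Air 1-2).

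The 15 probes called between the sexes went with a higher floor on male arrays. After local centring a probe kept a median share of 0.961 of its difference (quartiles 0.826 and 1.01), and the median difference went from 0.44 to 0.41. That share lay above the 0.8 set as the bound against spot position as the whole cause. However, local centring subtracts the median deviation of surrounding spots, and 84.6% of probes have compressed differences near the offset's floor. It may take too little from brighter probes such as most of the 15, so it cannot exclude spot position. Of the 15, 12 lie in the printed field that holds 48.8% of clone spots. Under median scaling, which leaves the floors unequal, the median share was 0.799 (quartiles 0.760 and 0.833, lowest 0.696) and the median difference 0.808 of its size. These lie on either side of the 0.8 set as the bound against the floor and above the 0.5 set as the bound for it, so floor and sex cannot be told apart for these probes. A biological difference between the sexes may account for part of the calls and stays open.

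Neighbouring clone spots varied together between EtOH and air: their test statistics, the difference over its SE, correlated at 0.585 for the average effect. Uneven signal across the array surface is a candidate explanation. The EtOH minus air differences of genomic DNA control spots, not test statistics, correlated at 0.573 with those of the clones around them. Of 100 relabellings of treatment, the real one included, 11 gave as high a correlation of neighbouring test statistics, with 0.665 as the highest other. The bound set beforehand counted this against exposure to EtOH, but a missed threshold does not show that exposure had no part, so exposure stays open.

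Sets of arrays varied together across groups. Clone deviations correlated 0.327 higher within sets than between them, which describes the pattern and does not name its source. A shared array surface or spotting, which the files used here do not record, stays open. Shared RNA or animals are argued against by the labels, which give every array its own pool of 2 mice. Of the 22 pairs within sets, 9.09% share sex, line and selection replicate, but arrays that share these are separate pools too, so that share decides little. Each set held a single selection replicate number, and what arrays of equal number had in common was not tested. No biological explanation was tested.

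Where the real split called 0 probes, every other split reaches that count by construction, 35 of 35 in each stratum, and the count says nothing about chance; the highest other split called 32 in female WSP, 0 in female WSR and 1 in male WSP and in male WSR. In female WSP 14 splits called any probe and the highest called 32, a sign of some structure among these arrays that no test here identified. Of its 8 arrays, 2 belong to array sets. Its 4 air arrays correlated with the others of their group at medians of 0.944 to 0.954, against a median of 0.973 over all 32 arrays. These air arrays enter the EtOH effect in female WSP, the averages and interactions that include it, and the line and sex differences in air controls. Genes named in several of these, such as SA rat hypertension-associated homolog, are not separate findings. Other air arrays are shared too. ARL6 is named in male WSP and in the line difference, and calcineurin interacting protein 1 in the line difference and the interaction by line. Likewise by construction, 100 of 100 splits reach the real 0 for the average effect (highest other 1), females (9), males (3), WSP (1), WSR (9), the interactions by sex (1) and by line (1), and the line difference (0). At an unadjusted p under 0.05 in limma, 3 of 35 splits gave as many as the real 543 in female WSP (highest other 578), 23 as many as 141 in female WSR (427), 9 as many as 289 in male WSP (395) and 4 as many as 159 in male WSR (215). For the average effect 7 of 100 gave as many as 353 (443), and for line 24 of 100 as many as 252 (485). Chance could not be excluded for any of these counts at an unadjusted p. For sex, 1 of 100 splits, the real split itself, gave 15 calls (highest other 1), and 1 gave 462 at an unadjusted p under 0.05 (highest other 430). That is the lowest share that 100 splits can give. It argues against chance under the main scaling, but the splits ignored the array sets, so chance is not excluded.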

How the results depend on the processing

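Alternatives with array sets, local centring or 2 arrays left out were chosen after the results were seen, and the others beforehand. The cause was not tested for any value below, beyond the fewer arrays or probes that a setting names. Signal over background limits all comparisons, with 51.1% to 88.7% of clone spots above it. No slide, scan or lot was found in the files, so a batch block was not run. Random blocks and single selection replicates were not run for gene lists, nor random blocks for similarity.

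Female WSP gave 0 calls, and 1 without background correction, with an offset of 16, without the dimmest probes, without a trend and with array sets as a random block, 17 under median scaling, 31 under cyclic loess, 22 with the authors' values, 17 and 32 in selection replicates 1 and 2, 6 with array sets and median scaling, 4 with array sets and cyclic loess, and 6 without 2 arrays. Single selection replicates gave 1 call in female WSR (replicate 2), 1 and 1 in male WSP, and with replicate 1 1 for the average, 3 in males and 1 in WSR. The authors' values gave 9 in females. Line gave 3 under cyclic loess, 11 with the authors' values, 2 without a trend, 4 with array sets and 4 with array sets and cyclic loess. Sex gave 15, and 0 under median scaling and cyclic loess, 138 with the authors' values, 6 with only the arrays compared, 30 with array weights, 23 without a trend, 0 with array sets and median scaling, 6 with array sets and cyclic loess, 2 with local centring and median scaling, 2 with both and array sets, and 7 without 2 arrays. Median scaling called 1 gene list.

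With selection replicate as a replicate block, sex gave 17 calls, including all 15, and no other call changed. Pool pairs, which share only a number (r from -0.03 to 0.07), gave 8 for sex as a replicate block. The equal numbers of the lines correlated at -0.12 in females and 0.30 in males.

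Similarity reversed for female WSP and male WSR to -0.03 under median scaling (-0.0297), -0.00572 under cyclic loess, -0.00917 without the dimmest probes, -0.0311 with local centring, -0.0940 with that and median scaling and -0.0259 without 2 arrays. It reversed for female and male WSP to 0.0343 under cyclic loess, 0.0407 with the authors' values and 0.0227 in selection replicate 1, for female and male WSR to 0.426 in replicate 1, for female WSP and WSR to -0.107 in replicate 2, and for male WSP and WSR to -0.603 in replicate 2 and -0.141 without 2 arrays. Among named genes, guanylate nucleotide binding protein 2 reversed to 0.0123 and plakophilin-3 to -0.232 in replicate 2, gene trap locus 3 to -0.0574, -0.0898, -0.00457 and -0.0491 under local centring alone, with median scaling, with array sets and with both, and transcription factor-like 1 to -0.0108 under local centring with median scaling. Of the other values of named genes, 3369 kept direction and side, 45 passed the threshold and 40 lost it.

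Leaving out each array gave 0 to 18 calls in female WSP, 0 to 2 in females, 0 to 1 in WSP, 0 to 2 for line, 0 to 15 for sex, 0 to 1 gene lists and 0 to 0 for the other comparisons. Similarity ran from 0.0375 to 0.177 for female WSP and WSR, -0.103 to -0.0216 for female and male WSP, -0.0410 to 0.0459 for female WSP and male WSR, 0.186 to 0.464 for female WSR and male WSP, -0.309 to 0.0110 for female and male WSR, and -0.147 to 0.211 for male WSP and WSR. The arrays behind these counts are named with the comparisons they moved.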

Other observations

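The tests after local centring and with array sets were chosen only after the results were seen. The 467 spots without identity gave 0 calls by limma in the EtOH comparisons, with 68.3% of their values above background. Adjacent clone spots correlated in their test statistics at 0.423 to 0.585 over the 13 comparisons, and at 0.125 to 0.208 after local centring. The consensus correlation within array sets was 0.509, against 0.00700 within populations.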
